A study of Mus musculus with 3 samples.

How the data were processed

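The series held 3 libraries of mouse primary T cells, all in 1 group, numbered 2, 3 and 4 as biological replicates in the labels. The deposited gene tables hold raw counts of read pairs per gene. Per the file headers, the authors counted pairs with featureCounts 1.4.6-p4 against GENCODE vM13 on mm10, over exons grouped by gene, with both ends required to be aligned and with reverse strand counting, so that antisense genes were separated by strand. The headers set no option for reads that align to several places, so near-identical gene copies and repeated genes such as histones, globins and ribosomal RNA are undercounted. The alignments they name carry the word star, the cell name Th0, the word activated, 0 h and replicate numbers that match the labels, while the labels themselves give only T-cell, a differentiation protocol for CD4+ T cells and no time. The aligner's version and settings are not given in the sources used here. The tables also give the summed exon length of each gene, and coordinates are those of the deposited tables. The text lists of files that came with each library were not used.

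The unit differed from the one planned for. The design, fixed before the data were examined, assumed expected counts and TPM from RSEM, and the tables hold whole counts. Counts were therefore used as deposited, with no rounding, and TPM were computed here from counts and exon lengths, so transcripts shorter than the merged exons are not modelled and very short genes are inflated. Genes under 200 bases held 3.38% of summed TPM. Symbols came from the given name table by Ensembl identifier without version (50376 of 50600 genes matched), and biotypes from GENCODE M21, whose build is also mm10. The 224 unmatched genes held 0.0115% of counts on average and stayed in library sizes.

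Genes were called detected at 1 TPM or more in all 3 libraries. Library agreement was Pearson's and Spearman's correlation across genes of log2(TPM + 1), with a chi-square test of each pair's counts over genes with a mean count of 10 or more. Variation among libraries was tested with edgeR 4.0.16 in R 4.3.3 by the goodness of fit of an intercept-only negative binomial model with TMM scaling and trended dispersion, over 13498 genes with a mean count of 10 or more, with Benjamini-Hochberg adjustment at 0.05. TMM factors were between 0.988 and 1.01. The test was run on simulated data with the real means and library sizes, the fitted trended dispersion and 200 genes changed in 1 library. It gave 0 calls with no gene changed and between 1 and 4 false calls otherwise. Every simulated gene lay on the trend that the test assumes. The false calls therefore do not show how many real genes would pass through scatter around the trend. Overlap of varying genes with each list was tested by Fisher's exact test, one-sided, among the genes tested. That test takes genes as independent, so its p-values may be too small for lists whose members vary together.

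Contrasts between genes (Cd4 with Cd8a and Cd8b1, all pairs of Tbx21, Gata3, Foxp3, Bcl6 and Eomes with a further regulator that is not reported here, and all pairs of Ifng, Il4, Il17a and Il2) used the difference of log2(TPM + 0.1) in each library and an exact two-sided sign-flip permutation test. Ratios of pooled counts were corrected for exon length, with a 95% exact binomial interval, and the floor was 3 counts. List levels were medians of log2(TPM + 0.1), and of TPM, over the members of 44 lists fixed before the data were examined, from which 2 ribosomal RNA genes were missing. List differences between libraries were medians of TMM-scaled log2 CPM with a prior count of 2, over members with a mean count of 10 or more in lists with at least 4, set against 10000 random lists matched on mean count in 20 bins. In a check with lists of 12 random genes, 5.80% lay outside the central 95% with no shift and 95.6% with a log2 shift of 0.20. The check does not cover lists whose members vary together. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

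The genes named were 17 core genes, the 4 members of each list with the highest mean TPM, members of lists below 1 TPM as needed, the 10 protein-coding genes of highest mean TPM outside mitochondrial and ribosomal protein genes, up to 10 genes with the smallest goodness of fit p at a mean of 1 TPM or more, and the 5 long non-coding genes of highest mean TPM. S1pr1, Cd44, Il2ra, Idi1, Rrm2, Tyms, Jun, Dusp1, Hsph1, Egr1 and the genes named in the closing section for a test were chosen after their values were seen. Alternatives were other detection thresholds, pseudocounts, scalings, count minimums, a common dispersion, other summaries of lists and each replicate left out. Counting on autosomes and mitochondrial genes alone, TPM without genes under 200 bases and protein-coding genes alone were added after seeing the data.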

Results

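RNA from mouse T cells of the C57BL/6NJ strain, taken as primary cells and not as a cell line, was sequenced in 3 libraries that the labels number as biological replicates 2, 3 and 4 of a single group. No second group was analysed here, so the questions open to the data were which T cell programmes the transcripts showed and which genes differed among the replicates. Totals were 47432940 gene counts in replicate 2, 59698913 in replicate 3 and 28340521 in replicate 4, and between 17595 and 19150 genes had at least 1 count. The labels give each library its own biosample but a single donor identifier for all 3, and so do not say whether they came from separate animals. The p-values of contrasts and of goodness of fit rest only on the spread between these libraries, which may be in part technical, although sex-linked genes divided them as given below. Those of Fisher's test take genes, not libraries, as units. Levels are means ± SD over the 3 libraries in TPM, counts corrected for gene length and scaled to a fixed total, and intervals and floors cover counting error only.

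The cells carried the transcripts of αβ T cells of the CD4 lineage. All 18 T cell identity genes were at 1 TPM or more in every library, led by the T cell receptor constant genes Trac at 3374 ± 63.1 TPM (SD, n = 3), Trbc2 at 2811 ± 75.5 TPM and Trbc1 at 1940 ± 92.2 TPM, and by the proximal receptor kinase Lck at 1715 ± 94.0 TPM. Cd3e, a CD3 chain, stood at 519 ± 14.3 TPM. Cd4, the coreceptor for MHC class II, reached 1044 ± 24.6 TPM and Zbtb7b, which encodes the CD4 lineage regulator ThPOK, 271 ± 11.8 TPM. Of the CD8 lineage genes, Cd8a was at 0.534 ± 0.182 TPM, Cd8b1 at 33.6 ± 3.00 TPM and the transcription factor gene Runx3 at 93.0 ± 15.7 TPM. Trbc1 and Trbc2 are near-identical copies, so reads could be split or lost between them.

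Cd4 (ENSMUSG00000023274.14, mm10 chromosome 6, 124864692 to 124888221, minus strand) had 159373 counts over the 3 libraries and Cd8a (ENSMUSG00000053977.13, chromosome 6, 71373427 to 71379173, plus strand) had 71. Cd4 exceeded Cd8a by 10.73 ± 0.42 on the log2(TPM + 0.1) scale (SD, n = 3), and the length-corrected ratio of pooled counts was 2025, with a 95% exact interval from 1605 to 2593. Against Cd8b1 the difference was 4.96 ± 0.15, with a pooled ratio of 30.7 (29.3 to 32.1). Both differences had the same sign in 3 of 3 libraries, with p = 0.25 in an exact two-sided sign-flip permutation test, which is the smallest p that 3 libraries allow, so no contrast between genes could pass 0.05. Over the 23 contrasts tested, the adjusted p of these 2 was 0.287 by the Benjamini-Hochberg method.

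Among the lineage regulators, Gata3 was the highest and Tbx21 the lowest of those reported here, in every library. Gata3, the Th2 regulator that is also needed for CD4 T cell development and maintenance, stood at 56.4 ± 4.43 TPM. Next came Bcl6, the regulator of follicular helper cells, at 18.4 ± 1.48 TPM, Foxp3, which defines regulatory T cells, at 6.52 ± 1.23 TPM, and Eomes, a T-box factor of cytotoxic and memory cells, at 4.50 ± 0.754 TPM. The Th1 regulator Tbx21 was at 1.27 ± 0.531 TPM. Gata3 exceeded Bcl6 by 1.61 ± 0.07 and Foxp3 by 3.11 ± 0.20 on the log2 scale, and the smallest gap, Foxp3 over Eomes, was 0.52 ± 0.09. All 10 pairs of these 5 genes kept their sign in 3 of 3 libraries, each with an exact two-sided p of 0.25 and an adjusted p of 0.287.

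Transcripts of Ifng, Il4, Il5, Il13, Il17a and Il22 were at or near the counting floor. Ifng, the Th1 cytokine, had 3 counts over the 3 libraries, Il4 of the Th2 set had 1 and Il17a of the Th17 set had 1. Il5, Il13 and Il22 had 0 counts, and 3 pooled counts would amount to 0.0517 TPM for Il5, 0.0659 TPM for Il13 and 0.0715 TPM for Il22. Il2, the T cell growth factor, had 98 counts and a level of 2.36 ± 0.428 TPM, and the pooled ratio of Ifng to Il2 was 0.027 with a 95% exact interval from 0.00548 to 0.0814. The Th17 cytokine Il17f was at 0.329 ± 0.222 TPM. Il2 exceeded Ifng, Il4 and Il17a in 3 of 3 libraries (exact two-sided p = 0.25, adjusted p = 0.287), while the contrasts among Ifng, Il4 and Il17a had no common sign and changed direction or vanished when a library was left out. Of the 21 cytokine genes, 6 were at 1 TPM or more in every library, and the highest were Tgfb1 at 116 ± 7.58 TPM, Lta at 75.4 ± 12.2 TPM, Osm at 52.2 ± 1.09 TPM and Tnf at 46.7 ± 5.49 TPM.

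**Figure D1:**
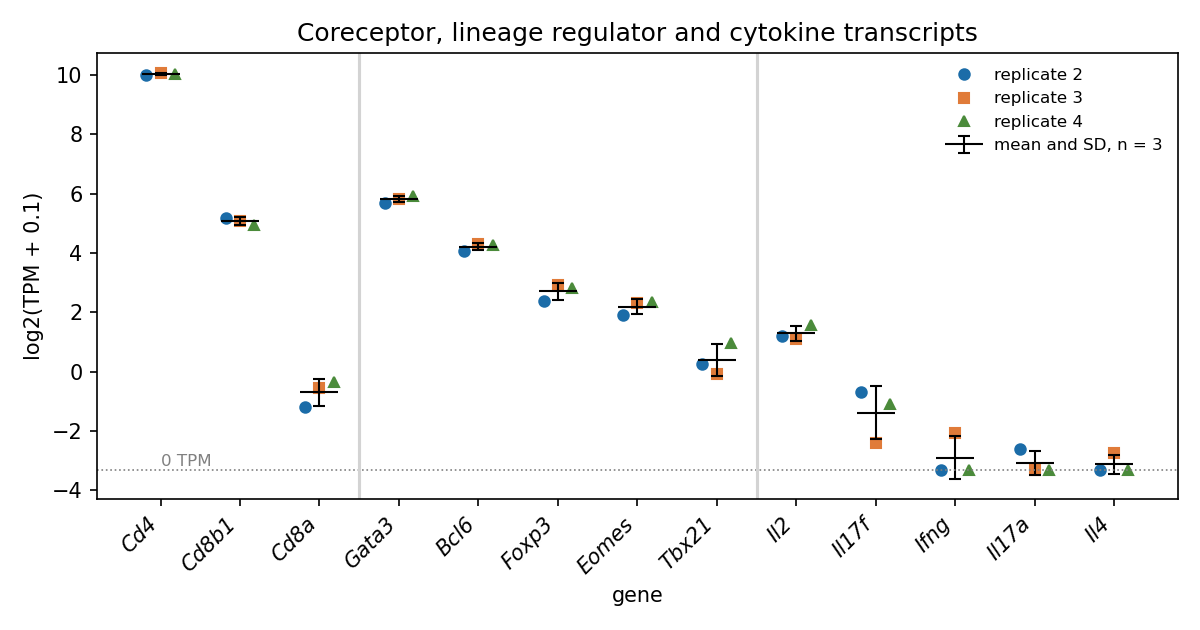
Levels of coreceptor, lineage regulator and cytokine transcripts in the 3 libraries, as log2(TPM + 0.1) on the vertical axis, with 1 coloured symbol per replicate and a black bar for the mean ± SD (n = 3). Cd4 stands at 1044 TPM and Cd8a at 0.534 TPM, Gata3 leads the regulators at 56.4 TPM, and Ifng, Il17a and Il4 lie at or near the dotted line of 0 TPM.

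In the Th1 list 5 of 10 members were at 1 TPM or more in every library, with the kinase gene Txk at 54.2 ± 4.27 TPM and Stat4 at 49.5 ± 1.24 TPM. In the Th2 list it was 5 of 11, with Stat6 at 387 ± 17.3 TPM and the interleukin 4 receptor gene Il4ra at 334 ± 8.75 TPM. The Th17 list had 6 of 16, with Stat3 at 137 ± 3.52 TPM and Batf at 119 ± 12.1 TPM, and Il23r, the interleukin 23 receptor gene, had 0 counts. The Treg list had 9 of 11, led by Tnfrsf18 at 94.99 ± 3.95 TPM, and the Tfh list 7 of 9, led by Btla at 132 ± 10.96 TPM. Of the γδ T cell genes only Trdc passed 1 TPM in every library, at 8.47 ± 1.77 TPM, while Tcrg-C1 was at 0.980 ± 0.296 TPM. In the thymocyte list Rag1 and Rag2, which encode the recombinase of antigen receptor genes, had 0 counts, where 3 pooled counts would be 0.0120 TPM for Rag1, and Dntt, the gene of terminal transferase, was at 26.8 ± 4.30 TPM.

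Genes of naive and quiescent T cells were among the highest lists. All 12 were at 1 TPM or more in every library, with a median of 487 ± 22.1 TPM. Tcf7, a transcription factor gene of naive and memory T cells, reached 2947 ± 117 TPM, Ccr7, the receptor that guides cells into lymph nodes, 1051 ± 37.6 TPM, and Klf2, a quiescence regulator, 649 ± 28.02 TPM. S1pr1, which directs exit from lymph nodes, was at 648 ± 28.5 TPM. All 14 activation genes also passed 1 TPM, but over a wide range. The inhibitor gene Nfkbia stood at 423 ± 14.2 TPM, Cd40lg at 280 ± 7.05 TPM and Myc at 149 ± 2.82 TPM, while Cd44, a marker of antigen-experienced cells, was at 24.4 ± 4.399 TPM and the high-affinity interleukin 2 receptor chain Il2ra at 3.93 ± 1.39 TPM.

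Of the cytokine receptors, 16 of 20 passed 1 TPM in every library, including Il7r at 679 ± 171 TPM, the common γ chain Il2rg at 646 ± 13.4 TPM, Il27ra at 503 ± 24.9 TPM and Il21r at 486 ± 14.4 TPM. Among chemokine receptors it was 7 of 14, and apart from Ccr7 only Cxcr4, at 345 ± 40.7 TPM, exceeded the 5.48 ± 0.553 TPM of Cxcr5. The inhibitory receptor list (6 of 8) was led by the regulator Tox at 33.5 ± 0.932 TPM and by Pdcd1, which encodes PD-1, at 12.9 ± 1.23 TPM. In the cytotoxic list (6 of 8) the perforin gene Prf1 was at 86.2 ± 4.18 TPM, against 0.565 ± 0.383 TPM for the granzyme gene Gzmb. All 5 TGF-β response genes were detected, with Ski at 281 ± 3.30 TPM, and of the 4 targets of the aryl hydrocarbon receptor only Tiparp was, at 19.3 ± 1.39 TPM.

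Of 14 S phase genes, 12 were at 1 TPM or more in every library, with a list median of 36.0 ± 1.00 TPM, the replication clamp gene Pcna at 124 ± 3.59 TPM and the helicase subunit gene Mcm4 at 98.2 ± 1.99 TPM. Other members were low, Rrm2 at 5.47 ± 1.48 TPM, Tyms at 2.79 ± 0.185 TPM, Gins2 at 0.851 ± 0.287 TPM and Cdc6 at 0.637 ± 0.203 TPM. Of 13 genes of G2 and mitosis, 7 passed, with a median of 1.23 ± 0.133 TPM, the kinase gene Plk1 at 4.07 ± 1.14 TPM and the proliferation marker Mki67 at 2.01 ± 0.284 TPM. Metabolic lists were high in all libraries, with 16 of 17 glycolysis genes and 14 of 14 nuclear genes of oxidative phosphorylation detected. Ldha, the lactate dehydrogenase gene, stood at 567 ± 9.23 TPM and the hexokinase gene Hk2 at 0.622 ± 0.129 TPM, while Atp5a1, a subunit of ATP synthase, was at 696 ± 27.6 TPM. All 13 cholesterol synthesis genes were detected, from Idi1 at 2.16 TPM to the regulator Srebf2 at 293 ± 13.8 TPM.

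Most genes of the stress and response lists were also detected, which alone does not show that a response was under way. The median detected protein-coding gene stood at 33.4 TPM. List medians were 8.35 TPM for hypoxia, 46.0 TPM for endoplasmic reticulum and amino acid stress and 40.5 TPM for the interferon response. They were 158 TPM for heat shock and 48.6 TPM for immediate early genes. The hypoxia list had 7 of 9 members detected, led by the kinase gene Pdk1 at 220 ± 24.0 TPM, and the list of endoplasmic reticulum and amino acid stress 7 of 9, led by Atf4 at 315 ± 40.2 TPM. All 13 interferon response genes were at 1 TPM or more, among them Bst2 at 238 ± 3.82 TPM and Isg15 at 76.8 ± 10.5 TPM. All 7 heat shock genes passed, led by Dnajb1 at 224 ± 37.7 TPM and Hsp90aa1 at 218 ± 41.8 TPM. Of 14 immediate early genes, the first to respond to stimulation, 11 passed, led by Zfp36 at 378 ± 26.6 TPM, Junb at 328 ± 82.2 TPM and Ier2 at 289 ± 12.3 TPM.

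Markers of other cell types were mostly low, with B cell and MHC class II genes the main exceptions. In the B cell list 9 of 10 genes were at 1 TPM or more in every library. Ighm, the constant gene of the IgM heavy chain (ENSMUSG00000076617.9, chromosome 12, 113418558 to 113422730, minus strand), reached 1223 ± 40.6 TPM, against 50.1 ± 14.8 TPM for the κ light chain gene Igkc, 18.6 ± 4.50 TPM for Ighd and 14.8 ± 2.31 TPM for the B cell receptor signalling gene Cd79a. In the list of dendritic cells and MHC class II, the invariant chain gene Cd74 was at 117 ± 22.6 TPM and H2-Eb1 at 30.9 ± 8.38 TPM, while the other 5 of its 9 members fell short of 1 TPM. The NK cell list passed only for Klrd1, at 29.4 ± 0.900 TPM, and the macrophage list for Cd68, at 13.3 ± 0.314 TPM, and 1 further gene, Lyz2, at 1.75 ± 0.418 TPM. Platelet genes were at 0 counts except Itga2b, at 3.50 ± 0.423 TPM, epithelial genes stayed below 1 TPM except Epcam, at 2.98 ± 0.113 TPM, and endothelial genes except Pecam1, which T cells also express, at 155 ± 1.498 TPM. None of the 7 neutrophil, 5 mast cell and basophil, 5 stromal and 7 erythroid genes passed 1 TPM in every library, with means up to 2.01 ± 1.37 TPM for the globin gene Hbb-bs.

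**Figure D2:**
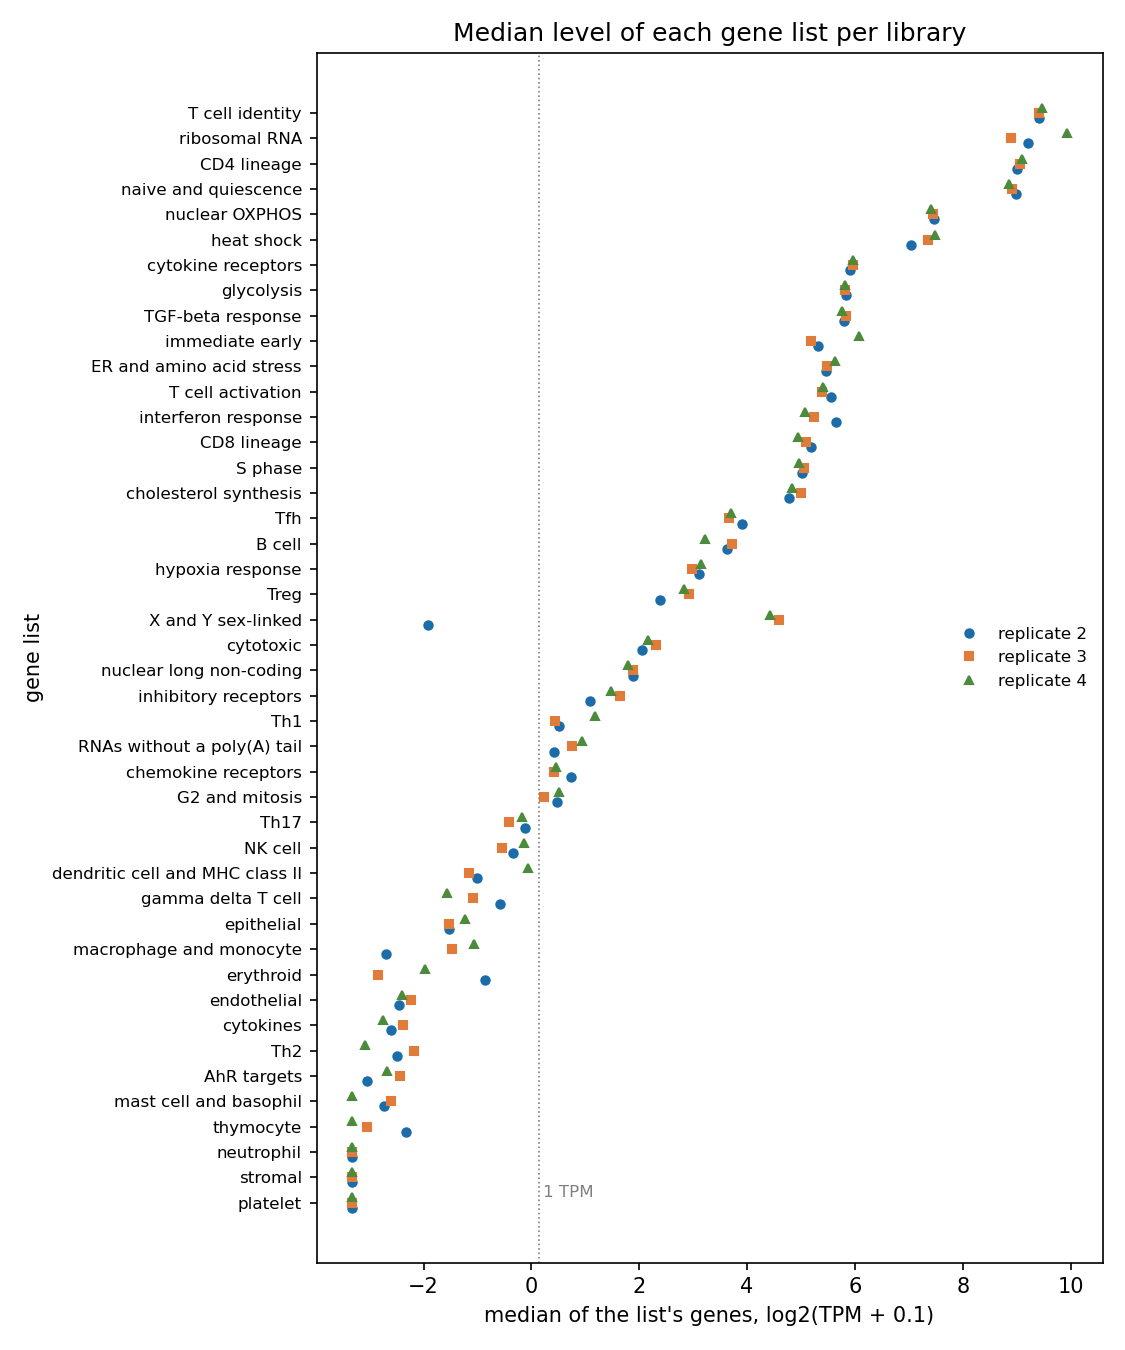
Median level of each of the 44 gene lists (vertical axis) in each library, as the median of log2(TPM + 0.1) over the list's genes, with 1 symbol per replicate and a dotted line at 1 TPM. T cell identity genes sit at a median of 9.44, and the list of X- and Y-linked genes is the one whose libraries lie furthest apart, with an SD of 3.71.

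The most abundant protein-coding transcripts outside the mitochondrial and ribosomal protein genes were the elongation factor genes Eef1a1, at 14327 ± 185 TPM, and Eef2, at 6182 ± 230 TPM, the actin gene Actb, at 8363 ± 240 TPM, and the MHC class I genes H2-K1, at 6249 ± 227 TPM, and B2m, at 5796 ± 335 TPM. They were followed by Tmsb4x, H2-D1, Coro1a, Tpt1 and Arhgap45, the last at 3235 ± 114 TPM. Mitochondrially encoded genes took 1.14 ± 0.0481% of counts and ribosomal protein genes 5.57 ± 0.218%. The highest long non-coding genes were Gm42418, at 2123 ± 137 TPM, Gm45552, at 681 ± 23.8 TPM, Gm26917, at 680 ± 261 TPM, 2410006H16Rik, at 309 ± 26.4 TPM, and the nuclear RNA Malat1, at 300 ± 20.6 TPM. Gm42418 and Gm26917 overlap ribosomal RNA sequence and are the 2 detected members of the ribosomal RNA list. Of 4 nuclear long non-coding RNAs 2 were detected, the other being Neat1 at 32.9 ± 5.88 TPM, and of 8 RNAs that lack a poly(A) tail 4 were, led by Rn7sk at 32.7 ± 5.10 TPM. Replication-dependent histone genes, whose transcripts also lack a tail, took 0.00497 ± 0.000552% of counts. The labels call the assay total RNA-seq and name a poly(A) library protocol, and both readings stand beside these values.

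The 3 libraries were close to each other in most genes. A total of 11820 genes, 10030 of them protein-coding, were at 1 TPM or more in every library. Across 50600 genes, which are not independent replicates, Pearson's r of log2(TPM + 1) was 0.995 between replicates 2 and 3, 0.994 between 3 and 4, and 0.993 between 2 and 4, with Spearman's rho between 0.919 and 0.928. To look for duplicate libraries, counts were compared by pair, and no pair agreed within sampling noise, with chi-square per degree of freedom of 16.9, 14.9 and 9.13 for replicates 2 and 3, 2 and 4, and 3 and 4, so none was merged. The common biological coefficient of variation was 9.24%.

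Sex-linked genes separated replicate 2 from replicates 3 and 4 more than any other list. Xist, the RNA that silences an X chromosome (ENSMUSG00000086503.3, chromosome X, 103460375 to 103483217, minus strand), was at 151 TPM in replicate 2 and at 0.221 and 0.399 TPM in replicates 3 and 4. The Y-linked helicase gene Ddx3y (ENSMUSG00000069045.11, chromosome Y, 1260771 to 1286629, minus strand) was at 0.248 TPM in replicate 2 and at 80.0 and 72.3 TPM in the others (edgeR goodness of fit, adjusted p = 9.98e-218). Eif2s3y, Kdm5d and Uty had the same order, with log2 ranges of 8.06, 8.16 and 7.13. All 5 genes of the list varied beyond the trend (Fisher's exact test, one-sided, p = 3.75e-12, adjusted over 44 lists to 1.65e-10). These 5 calls were lost in edgeR's test without replicate 2 and kept without replicate 3 or 4. The labels give no sex for any library.

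Over all genes, 72 of 13498 tested varied more among the 3 libraries than genes of their abundance did, by edgeR's goodness of fit at an adjusted p of 0.05, 58 of them protein-coding and 13 on the X or Y chromosome. Replicate 2 was the farthest from the mean for 34 of them, replicate 4 for 22 and replicate 3 for 16. Among the list genes, 14 of 297 passed, and 21 adjusted over the list alone. Besides the sex-linked genes, the 10 with the smallest p included Slc15a2, a peptide transporter gene (ENSMUSG00000022899.8, chromosome 16, 36750178 to 36784962, minus strand), at 1.30, 35.5 and 25.8 TPM in replicates 2, 3 and 4 (adjusted p = 2.90e-112, lost without replicate 2). They also included Mid1-ps1, a pseudogene annotated on chromosome Y, at 33.7, 7.46 and 0 TPM, an order opposite to that of Ddx3y. The count depended on the dispersion and on each library, with 312 genes under a common dispersion and 35, 39 and 46 without replicates 2, 3 and 4. In data simulated for this comparison, with every gene on the dispersion trend, 25% of genes changed 1.5-fold in 1 library were recovered, 72% at 2-fold and 92% at 4-fold.

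Heat shock and immediate early genes formed the other lists enriched among varying genes. Of the heat shock list 3 members passed, the inducible HSP70 genes Hspa1b, at 86.0, 23.9 and 237 TPM in replicates 2, 3 and 4, and Hspa1a, at 18.3, 3.26 and 61.9 TPM, and Hsph1, at 102, 163 and 151 TPM (one-sided Fisher's exact p = 5.02e-06, adjusted p = 7.36e-05 over 44 lists). Hspa1a and Hspa1b (chromosome 17, 34969190 to 34972156 and 34956436 to 34959238) are near-identical copies, so their separate values are uncertain. Fisher's test nevertheless counts them as separate genes. In the immediate early list 4 of the 13 genes tested passed, Fos at 30.8, 27.2 and 122 TPM, Jun at 51.7, 42.8 and 143 TPM, Junb at 277, 283 and 423 TPM and Dusp1 at 29.4, 31.0 and 46.1 TPM (one-sided Fisher's exact p = 5.13e-07, adjusted p = 1.13e-05), all highest in replicate 4. The calls of Fos, Jun and Junb were lost without replicate 4, that of Hsph1 without replicate 2, and that of Dusp1 whichever library was left out, while Hspa1a and Hspa1b passed in each case and had replicate 3, which was lower, as the farthest library. Egr1, at 69.8, 79.6 and 74.1 TPM, and Nr4a1, at 98.2, 100.01 and 105 TPM, did not pass. Replicate 4 was also the library with the highest Gm26917, at 974 TPM against 591 and 475 TPM in replicates 2 and 3, and the lowest total count.

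**Figure D3:**
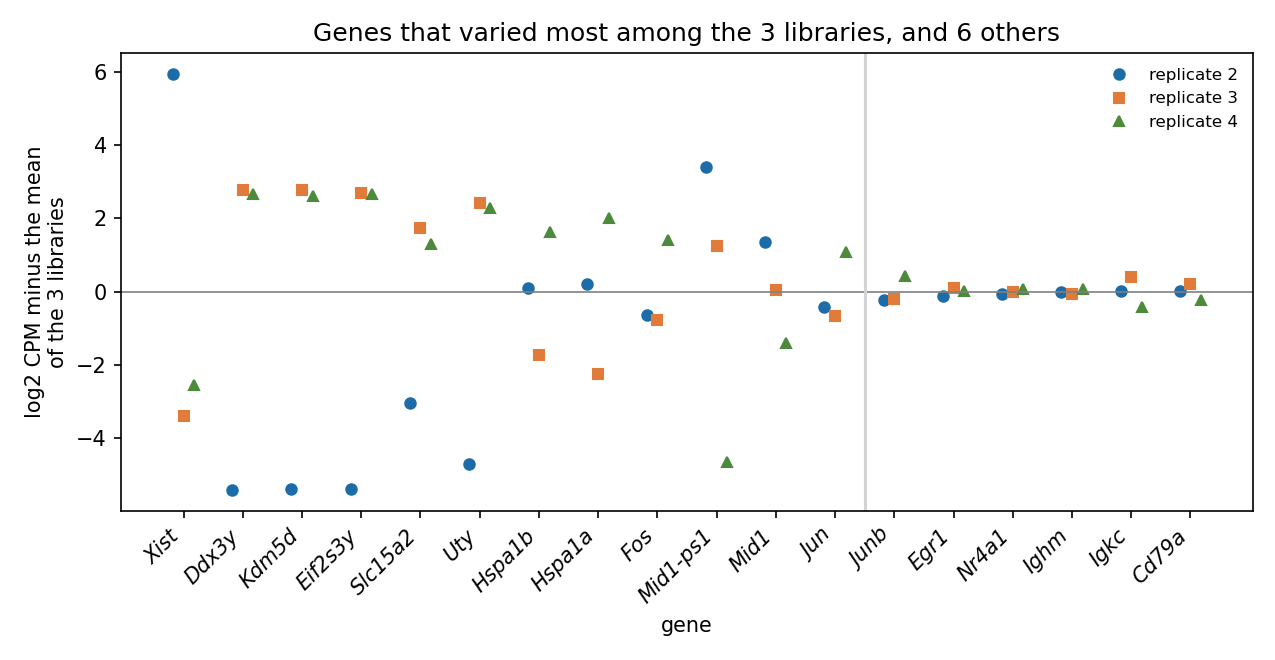
Deviation of each library from the mean of the 3, in log2 CPM (vertical axis), for the 12 genes with the smallest goodness of fit p (left of the grey line) and 6 further genes chosen after their values were seen, with 1 symbol per replicate. Xist is high and Ddx3y, Kdm5d, Eif2s3y, Slc15a2 and Uty are low in replicate 2, Fos and Jun are highest in replicate 4, and Egr1, Nr4a1 and Ighm lie close to 0 in all 3 libraries.

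As whole lists, besides the sex-linked genes, those given here differed between at least 1 pair of libraries by more than random lists of the same size and abundance. Heat shock genes were higher in replicate 4 than in replicate 2 for 7 of 7 (median log2 difference 0.48) and in replicate 3 than in replicate 2 for 5 of 7 (median 0.29), while replicate 4 minus 3 gave 0.03, inside the random range. As a list they thus set replicate 2 apart, unlike Hspa1a and Hspa1b. Immediate early genes were higher in replicate 4 than in replicate 2 for 11 of 13 (median 0.30) and than in replicate 3 for 12 of 13 (median 0.22). All 13 cholesterol synthesis genes had higher values in replicate 3 than in replicate 2, with a median log2 difference of 0.30 where the central 95% of random lists ran from -0.08 to 0.08, and all 13 were higher in replicate 4 than in replicate 2 (median 0.25). Interferon response genes were lower in replicate 3 than in replicate 2 for 10 of 13 (median -0.25) and in replicate 4 for 9 of 13 (median -0.27). B cell genes were lower in replicate 4 than in replicate 3 for 9 of 10 (median -0.61), and against replicate 2 had medians of 0.26 in replicate 3 and -0.36 in replicate 4. The MHC class II list had medians of -0.57 in replicate 4 against replicate 3 and 0.22 in replicate 3 against replicate 2. Against replicate 2, the hypoxia list had medians of -0.21 in replicate 3 and -0.24 in replicate 4, the Tfh list -0.14 and -0.20, and the G2 and mitosis list -0.37 in replicate 3. The T cell activation list was higher in replicate 4 than in replicate 3 for 11 of 14 genes (median 0.09, outside the central 95% of random lists) and than in replicate 2 for 10 of 14 (median 0.07, inside it). The naive list had medians of -0.05 in replicates 3 and 4 against replicate 2, and Il7r, at 875, 607 and 556 TPM in replicates 2, 3 and 4, was its single member that passed the goodness of fit test (edgeR, adjusted p = 0.0449), a call lost when any library was left out. In all, 24 of 87 combinations of list and library pair lay outside the central 95% of random lists. For lists of genes that vary independently 4.35 would be given by chance. Members of a list may vary together, which widens the spread of its median, and the pairs share libraries, so 24 and 4.35 cannot be compared directly. None of the cholesterol synthesis, interferon or B cell genes passed the goodness of fit test alone, adjusted over all genes tested.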

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

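The exclusion of X and Y chromosomes, of genes under 200 bases and of genes that are not protein-coding was chosen after seeing the data. The number of detected genes (8 alternatives, 9587 to 12743), of lists with a median of 1 TPM or more in every library (7 alternatives, 27 to 29) and of list differences outside random lists (2 alternatives, both 24) stayed within 1.5 times of the values with the planned settings. The number of varying genes was 72 as planned, 13 of them on the X or Y chromosome, and between 56 and 72 with other scalings or count minimums. Without X and Y it was 90, although those 13 genes could not be counted, so the rise on the remaining genes was larger than from 72 to 90. With X and Y, the number rose to 312 with a common dispersion. It was 35 to 46 when a replicate was left out, where fewer libraries were tested. Of those genes, 29, 39 and 38 without replicates 2, 3 and 4 were among the 72. The causes of the rises with a common dispersion and without X and Y were not tested. The lowest Pearson r was 0.993, and it was 0.983 with a pseudocount of 0.1, 0.980 over genes at 1 TPM or more on average, where fewer genes enter, and between 0.993 and 0.995 when a replicate was left out. Of 92 alternatives to the 23 contrasts, 89 kept the direction. The others concern genes with 1 to 3 counts: with a replicate left out, Ifng minus Il4 ran from 0 to 0.34, Ifng minus Il17a from -0.36 to 0.63 and Il4 minus Il17a from -0.36 to 0.29, which reflects where single counts fell. Values that RSEM gives as posterior means were an alternative not run, because the tables hold counts. No paired analysis was possible because there is 1 group. Depth limits the low cytokine and marker genes, and replicate 4 had the fewest counts.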

Other observations

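The tests of a single animal, of mixed cells, of X-linked paralogs, of B cells and of receptor activation were chosen only after the values they rest on had been seen, and the exclusion of animals of 1 sex rests on Xist and Y-linked values seen before its bounds were set. The tests of escape genes, of variable segments and of dissociation genes were set before their results were seen. The labels hold a single group, so no biological explanation was tested against another group for any of the 3 patterns.

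Several genes outside the lists differed between libraries and were chosen after their values were seen. Fkbp5, a target of the glucocorticoid receptor, was at 85.0 TPM in replicate 2 and at 42.5 and 41.1 TPM in replicates 3 and 4 (edgeR goodness of fit, adjusted p = 1.46e-12), and Bbc3, which encodes the pro-apoptotic protein PUMA, at 103, 58.5 and 55.3 TPM (adjusted p = 2.02e-05). Hsp90ab1, an HSP90 gene, went the other way, at 2221, 3457 and 3526 TPM (adjusted p = 0.0018). Cdk5rap1, at 31.2, 14.6 and 49.4 TPM, and Slc9a9, an endosomal exchanger gene, at 8.65, 25.1 and 6.80 TPM, each had replicate 3 as the farthest library. Mid1, the X-linked parent of Mid1-ps1, was at 16.6, 6.54 and 2.35 TPM.

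Xist and the Y-linked genes divided replicate 2 from replicates 3 and 4, while the labels give the 3 libraries a single donor identifier and no sex. A single animal behind all 3 libraries, animals of 1 sex, and male and female cells mixed within a library are argued against, since Xist in replicate 2 was 487-fold its mean in replicates 3 and 4, and the median of Ddx3y, Kdm5d, Uty and Eif2s3y in replicate 2 was 0.329% of theirs. The 5 genes set for the test as known to escape X inactivation all had values in replicate 2 above their mean in replicates 3 and 4. Their median lay 0.18 above that of 422 other X-linked genes on the log2 scale. That is between the bounds set for animals of 1 sex (0.1) and of both (0.2), so this test alone decided nothing. Kdm6a, an X-linked gene outside those 5, was higher in replicate 2 by 0.66. It was at 55.9, 34.6 and 34.3 TPM in replicates 2, 3 and 4 (edgeR goodness of fit, adjusted p = 0.000185). Reads of X-linked paralogs are argued against at Ddx3y, Kdm5d, Uty and Eif2s3y, whose counts in replicate 2 came to 0.116% of those of Ddx3x, Kdm5c, Kdm6a and Eif2s3x. They stay open for Mid1-ps1, Gm47283 and Gm21742, annotated on chromosome Y, with 553, 174 and 83 counts in replicate 2. Mid1-ps1 and Gm21742 did not follow the Y-linked genes tested, with 155 and 23 counts in replicate 3 and 0 in replicate 4. Gm47283 had 732 and 446 counts there. Mid1 on the X chromosome fell in the order of Mid1-ps1, with 1467, 732 and 126 counts in replicates 2, 3 and 4. These Y-annotated genes lie between 90753057 and 90844040, far from Ddx3y, Kdm5d, Uty and Eif2s3y, between 897788 and 1286629. They were not used to judge the sex of a library. Replicate 2 may come from a female and the others from males, and whether a library carries another sample's label stays open because no label gives the sex.

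Ighm was at a mean of 1223 TPM in cells with low levels of other B cell genes. B cells in the samples are argued against as the source of most Ighm transcripts, since Igkc stood at no more than 0.055 of Ighm in any library, although B cells carry light chain transcripts in abundance. Ighm was also lower by 0.13 in replicate 3 than in replicate 4 on the log2 scale, whereas the 9 other B cell genes tested were all higher, by at least 0.39. Heavy chain transcripts rearranged to a variable segment are argued against as most of them, since Ighv counts per Ighm count were 0.0078 of Igkv counts per Igkc count (380 and 86484 counts against 606 and 1076). The test does not cover transcripts without a variable segment. The source of most Ighm transcripts stays open.

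Fos, Jun and the Hspa1 genes were highest in replicate 4, with Fos 2.11 above the mean of the other libraries on the log2 scale and Hspa1b 2.42, although for Hspa1a and Hspa1b replicate 3, which was lower, was the farthest library. Activation through the T cell receptor in that library is argued against as the whole cause of the Fos and Jun values, since Egr1, Egr2, Egr3, Nr4a1, Nr4a3, Myc and Cd69 had a median difference of 0.033 (SD 0.13 over genes), far below that of Fos. A small shift stays open, since 11 of 14 genes of the T cell activation list were higher in replicate 4 than in replicate 3 (median 0.09, outside the central 95% of random lists) and 10 of 14 than in replicate 2 (median 0.07, inside it). As a whole, the heat shock list set replicate 2 apart, lower than replicates 3 and 4 by medians of 0.29 and 0.48, and differed by 0.03 between replicates 3 and 4. A response to handling of the cells may contribute, but 10 genes known to rise on tissue dissociation, of 14 set for the test, had a median difference of 0.19 (SD 0.24), higher in 8 of 10, which lies between the bounds set for its presence (0.3) and absence (0.1), and it stays open because the labels give no record of handling.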
